A study of Homo sapiens with 21 samples.

How the data were processed

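Total RNA of HEK293 Flp-In T-REx cells, a human embryonic kidney line built for inducible transgenes, was sequenced in 21 libraries that form 7 groups of 3 replicates. Parental cells received control siRNA or siRNA against SKIV2L, HBS1LV3 or HBS1LV1. Each of 3 stable lines that make a siRNA-insensitive protein (SKIV2L, HBS1LV3 or HBS1LV1) received the matching siRNA. Per the labels' protocols, siRNA was used at 25 nM, doxycycline was given for 48 hours, and RNA was isolated with TRI Reagent, treated with Turbo-DNase and depleted of ribosomal RNA with Ribo-Zero. Doxycycline was given to induce the exogenous protein, and the labels do not say whether parental cells received it. The comparisons of rescue lines with parental cells therefore do not separate re-expression from the stable line or from doxycycline. Libraries were strand-specific (dUTP), per the labels' protocols.

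The authors deposited 1 file of raw read counts per library, with 58387 gene symbols and 5 counters of reads without a gene. Per the submitters' processing notes, CASAVA 1.8.2, STAR 2.4.0, SAMtools 1.2-10, HTSeq 0.6.1, FastQC 0.11.3 and DESeq2 1.8.2 were used. The genome build, the annotation and the strand setting of the counting are not given in the sources used here, so a gene and an antisense or overlapping partner, or a near-identical copy such as a histone or ribosomal protein gene and its pseudogenes, may share reads. External ERCC RNA was added, per the labels' protocols, but 0 of the deposited count rows are spike-ins, so all levels are relative to the other genes of a library and a change in total RNA per cell cannot be seen. Counts of the HBS1L gene do not separate its splice variants.

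Counts in genes ranged from 3.51 to 11.9 M (mega) per library. In each library a share of reads outside annotated exons was computed as the no-feature counter over that counter, the ambiguous counter and the counts in genes. The counter of alignments that are not unique counts alignment records rather than reads, and its share was computed over all of these. Of the 58387 symbols, 22530 had no count in any library, and 15351 genes were tested after edgeR's filterByExpr. Counts were scaled with TMM factors and fitted in edgeR 4.0.16 (R 4.3.3) with 1 quasi-likelihood model of all 7 groups. Genes were called at an adjusted p under 0.05 (Benjamini-Hochberg over all genes tested), in 11 comparisons. Levels are given as CPM (counts scaled to the normalized library total) with the SD of 3 replicates, and log2 fold changes with a standard error (SE) taken from the quasi-likelihood F statistic. Replicate letters were not used to pair samples: of 63 pairs of libraries with the same letter in different groups, centred correlations ran from -0.418 to 0.683 and 16 were over 0.1. The HBS1LV3 and HBS1LV1 rescue libraries of the same letter correlated in all 3 pairs (0.162, 0.683 and 0.520), so these 2 groups are not independent of each other.

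The following were fixed before the data were examined: the groups, the comparisons, the alternatives, the 22 gene lists and the rule for the genes named. By that rule, each knockdown comparison names the 12 higher and 12 lower genes with the largest fold change among those called, with no overlap of the 2 groups' CPM values and a mean of at least 5 CPM in the higher group. The other comparisons name 6 higher and 6 lower genes. Clone, locus and small-RNA symbols were left out. Of the genes this rule names, 2 are not reported here. SKIV2L and HBS1L are always named. Up to 4 members of each list described are named, those with the lowest adjusted p, and 12 genes are named among those undone by rescue for both SKIV2L and HBS1LV3. The exact pattern of symbols left out, and the reading that the latter genes need non-overlapping CPM values in all 4 comparisons, were settled after values were seen.

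Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 22 lists of a comparison, and again with an estimated correlation, with fry and with the replicate letter as a block. The lists are SKI complex, HBS1L and PELO; RNA exosome; 5-prime-to-3-prime decay and deadenylation; nonsense-mediated decay factors; known nonsense-mediated decay targets; snoRNA host genes; no-go decay and ribosome quality control; integrated stress response; unfolded protein response of the endoplasmic reticulum; interferon-stimulated genes; replication-dependent histones; cytosolic ribosomal proteins; mitochondrially encoded mRNAs; G1/S and DNA replication; G2/M and mitosis; p53 targets; immediate early and AU-rich mRNAs; cholesterol synthesis; hypoxia and glycolysis; extracellular matrix and adhesion; RNA sensing and nucleic acid surveillance; and markers of other cell types. Some genes are members of more than 1 list, for example GAS5 and ATF3.

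A knockdown effect was counted as undone when a gene was called in the knockdown against control siRNA and called in the opposite direction in the rescue line against the knockdown. These comparisons share the knockdown libraries, and all knockdown comparisons share the 3 control libraries. Overlaps are therefore set beside counts from 20 simulated data sets with unchanged groups, and from 20 with the observed knockdown effects and no undoing. The simulations draw each gene on its own and hold no library property that moves many genes together.

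The fit was tested on simulated data before use. For SKIV2L knockdown against control siRNA, with 200 of 15351 genes changed, it called 27.5% of genes raised 1.5-fold, 70% of genes raised 2-fold and 58.3% of genes lowered to 0.5-fold, and 4 unchanged genes. In a simulated data set of 14935 genes for the same comparison, camera called the list that had been shifted (adjusted p = 1.17e-37) and 0 of the other lists. Both simulations draw each gene on its own, so they cannot show false calls from genes that move together. In the data the estimated correlation for this comparison was 0.694 for histones and 0.719 for cytosolic ribosomal proteins.

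For the search of 7-base words, 3' UTRs came from GENCODE v29 and genes were matched by symbol, 36055 directly and 1061 through an older symbol. No coordinates were used. Of 12855 protein-coding genes tested, 98.6% had a 3' UTR of at least 50 bases, and 12682 genes and 16254 words present in at least 50 genes were searched (Biostrings 2.70.1). Words were ranked by the z value of a rank-sum comparison of the knockdown log2 fold changes of genes with and without the word, after a fit on 3' UTR length, or on length and GC content. A word found in the parental knockdown was then tested in the rescue lines, which share no library with the search, with 100000 permutations, two-sided, whose smallest possible p is 1e-05. On fold changes shuffled over genes for SKIV2L knockdown, with 400 of 12682 genes shifted, the shifted word ranked 1.

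The alternatives were DESeq2 1.42.0, RLE factors, no low-count filter, a filter of at least 1 CPM in at least 3 libraries, the 6 libraries of a comparison alone, the replicate letter as a block, thresholds of 0.1 and 0.01 for counts of overlap, and each library left out in turn. Scaling to spike-ins was not run, as the files hold none. After the data were seen, a covariate of each library's share of reads outside annotated exons, a fit without the 2 libraries with the highest share, a fit without the SKIV2L rescue libraries, RLE factors for the gene lists, the correction for GC content, the match through older symbols and the correlation over different replicate letters were added. The share of reads outside annotated exons does not overlap between rescue line and knockdown for SKIV2L and for HBS1LV3. The covariate may therefore also take up effects of rescue.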

Results

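The series measured gene expression by RNA sequencing in HEK293 cells in which factors that bring RNA to the cytoplasmic exosome had been silenced. SKIV2L is the helicase of the SKI complex, which feeds RNA to the exosome, and HBS1LV3 and HBS1LV1 are proteins made from splice variants of HBS1L. The stated aim was to find transcripts degraded by assemblies of SKI, HBS1LV3 and the exosome. There were 4 groups of parental cells (control siRNA, SKIV2L knockdown, HBS1LV3 knockdown, HBS1LV1 knockdown) and 3 groups of rescue lines, with n = 3 in each.

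Mean counts in genes were 9.17 ± 0.537 M (mega, SD, n = 3) with control siRNA and between 8.89 and 10.6 M in the other groups, except for the SKIV2L rescue line with 4.91 ± 1.25 M. Non-unique alignments made up 93.2 ± 2.00% of the records of the SKIV2L rescue libraries and 47.4 ± 0.947% of those of control siRNA. The 2 libraries with the most reads outside annotated exons were HBS1LV3 rescue replicate B (24.8%) and HBS1LV1 rescue replicate B (17.9%), against 11.6 ± 0.693% with control siRNA. The small nuclear RNA RN7SK took 10.4 to 19.7% of the counts in genes and the mitochondrial ribosomal RNA MT-RNR2 11.1 to 21.5%. The first 3 principal components held 25.3%, 21.2% and 16.2% of the variance of log2 CPM.

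**Figure D1:**
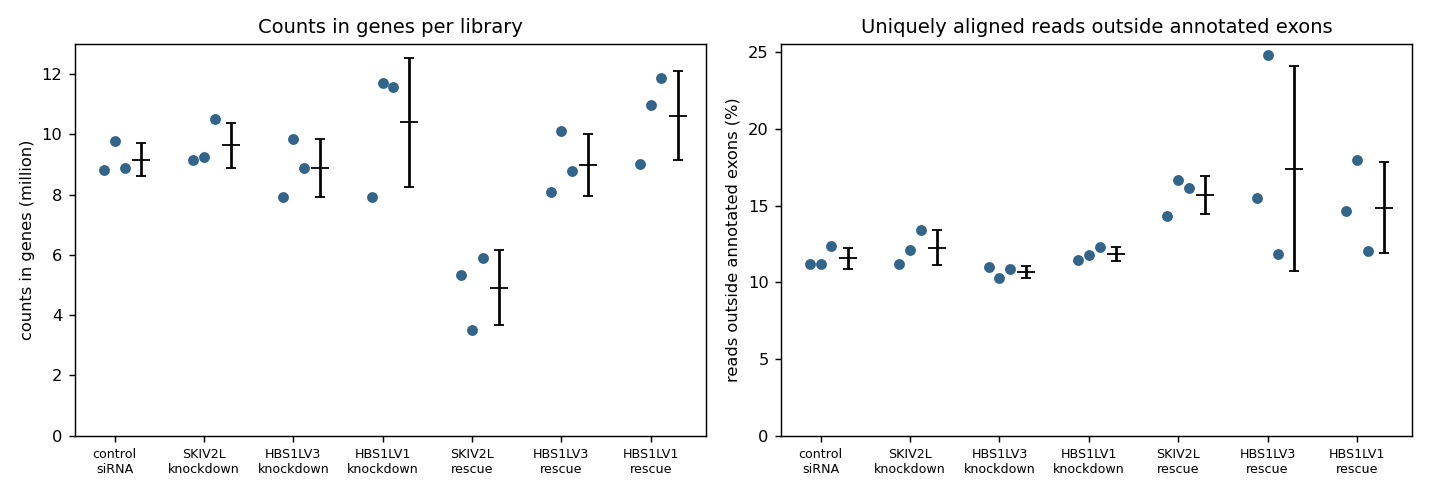
Counts in genes in M (mega, left) and reads outside annotated exons in percent (right) of each library; points are the 3 replicates of a group, and the bar beside them is the mean with its SD. The SKIV2L rescue libraries hold 3.51 to 5.90 M counts, and HBS1LV3 rescue replicate B has 24.8% of reads outside annotated exons.

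The targeted genes were measured first. SKIV2L stood at 66.7 ± 2.57 CPM (SD, n = 3) with control siRNA and at 20.4 ± 3.56 CPM in SKIV2L knockdown, a log2 fold change of -1.71 (SE 0.175, adjusted p = 4.38e-07, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). In the SKIV2L rescue line it reached 1723.9 ± 174 CPM. HBS1L fell from 30.0 ± 2.57 CPM with control siRNA to 19.0 ± 2.80 CPM in HBS1LV3 knockdown (log2 fold change -0.66, SE 0.149) and to 12.4 ± 0.737 CPM in HBS1LV1 knockdown (log2 fold change -1.27, SE 0.151). It reached 449 ± 20.7 CPM in the HBS1LV3 rescue line and 443 ± 56.9 CPM in the HBS1LV1 rescue line. These counts cover all HBS1L variants, so they do not show which variant was lowered or raised. In HBS1LV1 knockdown SKIV2L was higher (log2 fold change 0.47, SE 0.165, edgeR adjusted p = 0.0374), a call that was lost without control siRNA replicate A (adjusted p = 0.111). HBS1L did not pass the test in SKIV2L knockdown (log2 fold change -0.28, SE 0.144, edgeR adjusted p = 0.219).

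**Figure D2:**
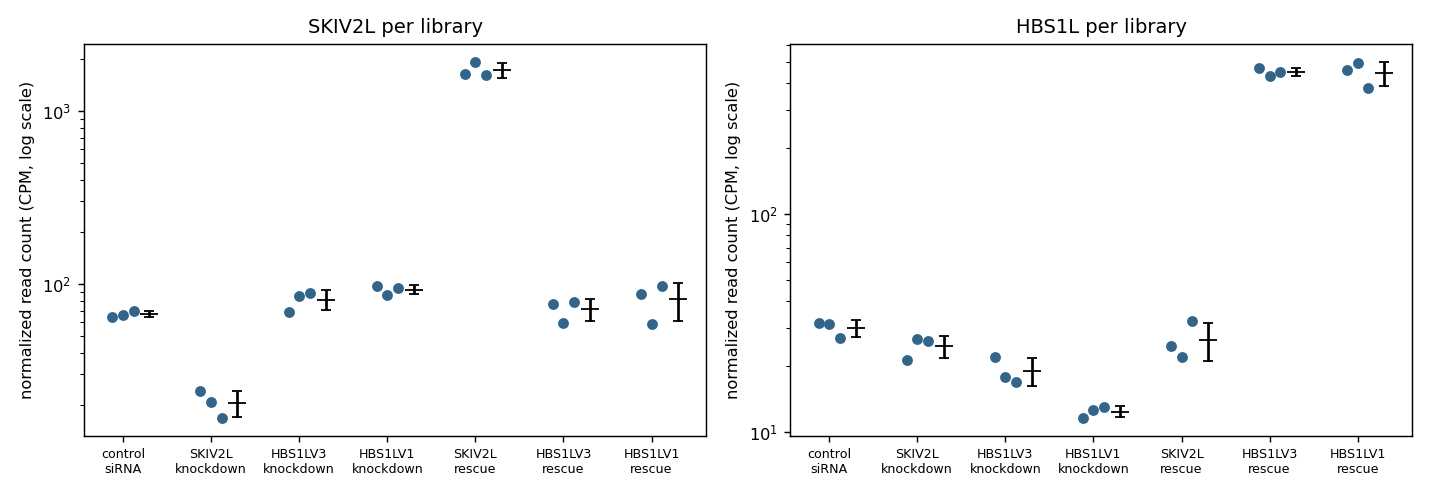
Normalized read counts (CPM, log scale) of SKIV2L (left) and HBS1L (right) in each library; points are the 3 replicates of a group, and the bar beside them is the mean with its SD. SKIV2L averages 20.4 CPM in its knockdown and 1723.9 CPM in its rescue line, and HBS1L averages 12.4 CPM in HBS1LV1 knockdown and 443 CPM in the HBS1LV1 rescue line.

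SKIV2L knockdown was compared with control siRNA to ask which transcripts change with siRNA against the SKI helicase. Alone, this comparison does not separate loss of SKIV2L from other effects of the siRNA. Of the genes called, 67.6% of the higher and 67.3% of the lower were called alike in the rescue line against control siRNA. Effects undone by rescue are counted below. TPM4, a tropomyosin of the actin cytoskeleton, rose 7.01-fold, from 23.4 ± 1.48 to 164 ± 14.3 CPM (SD, n = 3; log2 fold change 2.81, SE 0.13). The kinesin KIF1C rose from 62.7 ± 5.42 to 269 ± 24.0 CPM (log2 fold change 2.10). TOMM22, a receptor for protein import into mitochondria, rose from 23.5 ± 0.816 to 89.8 ± 8.32 CPM (1.93). The smooth muscle actin ACTA2 rose with a log2 fold change of 1.73 (SE 0.211). COL3A1 (2.25), PIR (2.15), MED11 (2.07), SETD7 (1.804), MMP24 (1.79), TUFT1 (1.76) and UNKL (1.71) were other large rises by log2 fold change. The tight-junction protein F11R fell from 11.8 ± 1.39 to 1.84 ± 0.246 CPM (log2 fold change -2.66, SE 0.241). AKR1B1, the aldose reductase, fell from 137 ± 10.4 to 34.3 ± 3.07 CPM (-2.002), and the proteasome subunit PSMD14 from 31.9 ± 0.729 to 9.88 ± 0.844 CPM (-1.69). The inflammasome sensor NLRP1 (-2.48), QDPR (-2.53), TMEM150A (-1.99), UBE2E2 (-1.96), OIP5 (-1.86), HIGD1A (-1.84), RRS1 (-1.74), SKIV2L itself and CHAC1 (-1.69) were the other large falls by log2 fold change.

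Of the extracellular matrix and adhesion list, 9 of 30 measured genes were higher and 1 was lower in SKIV2L knockdown, and 10 and 1 were called when adjusted over the list alone. The basement membrane collagens COL4A1 (log2 fold change 1.64, SE 0.117) and COL4A2 (0.70, SE 0.122) rose, as did COL6A1 (0.93, SE 0.173). The list as a whole was higher (camera adjusted p = 3.21e-05), with an adjusted p = 0.0562 with an estimated correlation. Cholesterol synthesis genes were lower, 8 of 22 with 2 higher (12 lower and 2 higher adjusted over the list alone; camera adjusted p = 0.00052, and adjusted p = 0.0141 with an estimated correlation). They included the synthase HMGCS1 (log2 fold change -1.05, SE 0.129), HSD17B7 (-1.14), the transcription factor SREBF2 (-0.95) and the epoxidase SQLE (-0.84). Replication-dependent histones were lower in 15 of 44 and higher in 0 (23 lower adjusted over the list alone; camera adjusted p = 6.82e-09, but adjusted p = 0.392 with an estimated correlation). HIST1H2AD (-1.26), HIST1H2BF (-1.24), HIST1H2BC (-1.06) and the linker histone HIST1H1E (-0.84) were among them. Histones made up 1.36 ± 0.215% of normalized counts in SKIV2L knockdown and 2.21 ± 0.182% with control siRNA.

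Among decay factors, 3 of the 6 measured genes of the list of the SKI complex, HBS1L and PELO were called in SKIV2L knockdown. SKIV2L and the SKI subunit WDR61 (log2 fold change -0.41, SE 0.117) were lower, and the ribosome rescue factor PELO was higher (0.56, SE 0.11). The list holds the target of the siRNA among its 6 genes, so its call says nothing on the partners. Of 16 exosome genes, 2 were lower, the cofactors C1D (-1.56, SE 0.227) and MPHOSPH6 (-0.66, SE 0.177), and 14 were not called. Of 28 genes of 5-prime-to-3-prime decay and deadenylation, 5 were lower, among them PAN2 (-0.58), CNOT6L (-1.03), CNOT6 (-0.75) and DCPS (-0.65). For each of these 3 lists the camera call (adjusted p = 0.0394, 0.0115 and 0.0408) was lost with an estimated correlation (adjusted p = 0.112 for each). Of the unfolded protein response list, 3 of 18 genes were higher, the chaperones CALR (1.202, SE 0.11), HYOU1 (0.53) and HSPA5 (0.55). Of 25 G2/M and mitosis genes, 3 were lower, namely AURKA (-0.85), CCNB1 (-0.69) and KIF20A (-0.42), and 1 was higher, BIRC5 (0.35). The camera adjusted p of these lists was 0.0303 and 0.0115, and adjusted p = 0.112 and adjusted p = 0.308 with an estimated correlation.

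In all, 1240 genes were higher and 989 lower in SKIV2L knockdown, 327 and 199 of them by more than 2-fold, of 15351 tested with edgeR. The count was 1479 without SKIV2L knockdown replicate A and 1480 without replicate B, and the calls of CNOT6L, CNOT6, DCPS, WDR61, MPHOSPH6, HSPA5, KIF20A and BIRC5 were each lost when 1 library was left out, as were those of RAB6B, MATK, KREMEN2, LARP4B, TUBB3, SIK2 and GINS2, which are described with the effects of rescue. The total was 3869 with the share of reads outside annotated exons as a covariate.

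**Figure D3:**
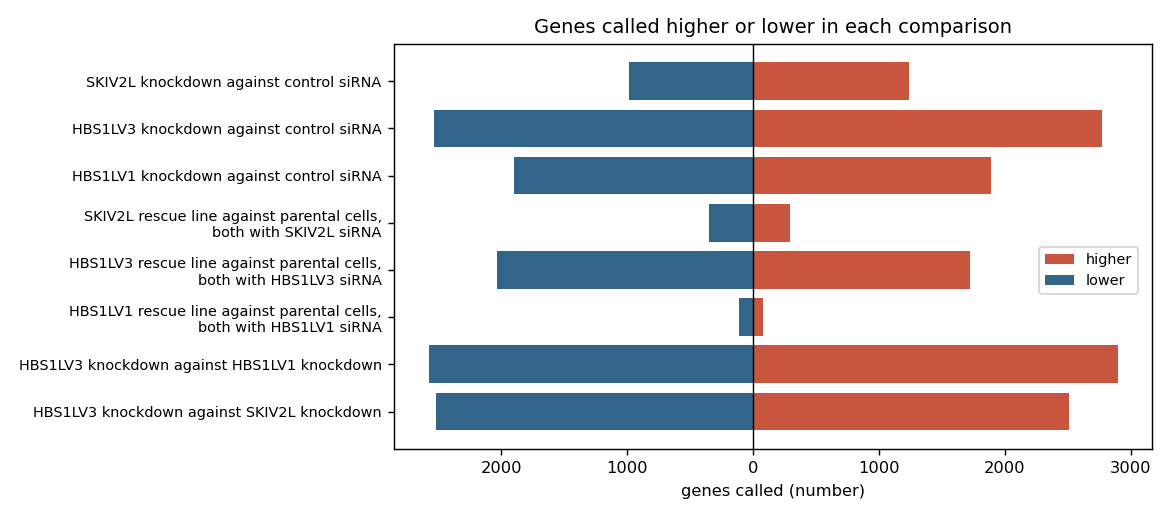
Number of genes called higher (right of 0) and lower (left of 0) in 8 comparisons of 3 against 3 libraries, edgeR adjusted p under 0.05. HBS1LV3 knockdown has 2775 higher and 2534 lower genes, and the HBS1LV1 rescue line has 77 and 108 against its knockdown.

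HBS1LV3 knockdown was compared with control siRNA to ask which transcripts change with siRNA against the variant named in the aim. Here too, loss of the target is not separated from other effects of the siRNA. Of the genes called, 49.5% of the higher and 60.8% of the lower were called alike in the rescue line against control siRNA. The integrated stress response, the program that follows phosphorylation of eIF2 alpha, was higher in 18 of 25 genes and lower in 2, with the same counts adjusted over the list alone (camera adjusted p = 3.17e-13, and adjusted p = 0.00478 with an estimated correlation). DDIT3, the transcription factor CHOP, rose from 8.23 ± 0.791 to 32.6 ± 0.490 CPM (SD, n = 3; log2 fold change 1.98, SE 0.142). DDIT4 (1.96), SESN2 (1.99) and PPP1R15A (1.76) rose as well. Host genes of small nucleolar RNAs rose in 15 of 18 and fell in 1 (the same adjusted over the list alone; camera adjusted p = 1.04e-14, and adjusted p = 0.0299 with an estimated correlation). SNHG7 went from 85.9 ± 12.1 to 430 ± 46.5 CPM (log2 fold change 2.32, SE 0.184), and SNHG8 (1.62), SNHG3 (1.42) and SNHG1 (1.23) followed. Known targets of nonsense-mediated decay, some of which are the same genes, rose in 14 of 24 and fell in 2 (15 and 2 adjusted over the list alone; camera adjusted p = 1.83e-05, and adjusted p = 0.0307 with an estimated correlation), with GAS5 at 1.10, NAT9 at 1.26 and ATF4 at 1.02 on the log2 scale.

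Targets of p53 were higher in HBS1LV3 knockdown in 13 of 20 genes and lower in 1, over all genes and adjusted over the list alone (camera adjusted p = 3.41e-09, and adjusted p = 0.000189 with an estimated correlation). BAX, which permeabilizes mitochondria in apoptosis, rose from 27.0 ± 1.18 to 146 ± 13.3 CPM (log2 fold change 2.43, SE 0.157). FDXR (2.30), TP53I3 (1.63) and BTG2 (1.32) rose as well. Genes of RNA sensing and nucleic acid surveillance were lower in 8 of 16 and higher in 1 (9 and 1 adjusted over the list alone; camera adjusted p = 0.000961, and adjusted p = 0.0307 with an estimated correlation). SAMHD1, which degrades deoxynucleotides, fell by 1.84 on the log2 scale, RNASEH2B by 1.53, the RNA editor ADAR fell by 0.95 and the adaptor MAVS fell by 0.62. Cholesterol synthesis genes were lower in 11 of 22 and higher in 3 (12 and 3 adjusted over the list alone; camera adjusted p = 0.0078, and adjusted p = 0.0299 with an estimated correlation). MSMO1 (-3.09, SE 0.216) and HMGCS1 (-1.04) fell, while FDPS (0.78) rose.

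Cytosolic ribosomal protein genes were higher in 49 of 77 in HBS1LV3 knockdown and lower in 1 (57 and 1 adjusted over the list alone). Their median log2 fold change was 0.43 (camera adjusted p = 2.61e-07, but adjusted p = 0.543 with an estimated correlation), and their share of normalized counts was 10.6 ± 0.633% against 7.60 ± 0.689% with control siRNA. RPL11 (1.02), RPL28 (1.05) and RPL13A (0.87) rose, and RPL14 was the exception, falling from 363 ± 37.6 to 64.4 ± 2.61 CPM (-2.50, SE 0.143). Replication-dependent histones were higher in 11 of 44 and lower in 0 (the same adjusted over the list alone; camera adjusted p = 0.0027, but adjusted p = 0.625 with an estimated correlation). HIST1H2BI (1.37), HIST1H3E (0.79), HIST1H2BB (2.29) and HIST1H3C (2.47) were among them, the last 2 at means of at most 5.07 CPM. Across all genes with a known length, log2 fold changes of this comparison had a Spearman rho of -0.204 with the length of the longest transcript.

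The largest rises in HBS1LV3 knockdown included genes at a low level with control siRNA. COL17A1 went from 0.323 ± 0.122 to 5.36 ± 0.193 CPM (log2 fold change 4.02, SE 0.297) and FRMPD2 from 0.356 ± 0.336 to 5.86 ± 1.10 CPM (3.997, SE 0.436), with 9 and 10 counts over the control libraries. ACTL8 (3.24), INPP5D (3.04), HIST1H3PS1 (2.75), PVRL4 (2.74), the stress cytokine GDF15 (2.67), INHBE (2.59), GRHL3 (2.57), FOSL1 (2.54), the cytokine LIF (2.49) and KANK3 (2.45) followed by log2 fold change. Among the largest falls, ATP5B, a subunit of the mitochondrial ATP synthase, went from 929.5 ± 52.8 to 163 ± 7.48 CPM (log2 fold change -2.51, SE 0.132), and ADIPOR1 from 132.5 ± 12.6 to 24.1 ± 2.17 CPM (-2.46). PEF1 (-2.48), ECI2 (-2.90), CBFB (-2.84), SNX10 (-2.79), TMEM64 (-2.77), TPRG1L (-2.52), ATP6V1E1 (-2.51) and TCTN3 (-2.48) were the others by log2 fold change. In all, 2775 genes were higher and 2534 lower with edgeR, 925 and 751 of them by more than 2-fold. Non-unique alignments (51.8 ± 1.76%) and ambiguous reads (27.0 ± 1.15%) in these libraries were above each control library.

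HBS1LV1 knockdown was compared with control siRNA as the counterpart with the long HBS1L variant. The integrated stress response was again higher, in 16 of 25 genes with 1 lower (18 and 1 adjusted over the list alone; camera adjusted p = 2.26e-17, and adjusted p = 0.00214 with an estimated correlation). TRIB3 went from 50.6 ± 6.69 to 319 ± 15.6 CPM (SD, n = 3; log2 fold change 2.65, SE 0.205), DDIT3 from 8.23 ± 0.791 to 48.8 ± 1.67 CPM (2.57), and ATF3 (2.20) and PPP1R15A (2.14) rose too. The unfolded protein response of the endoplasmic reticulum was higher in 9 of 18 genes and lower in 1 (12 and 1 adjusted over the list alone; camera adjusted p = 4.55e-05, and adjusted p = 0.00587 with an estimated correlation), with DERL3 at 1.28, HERPUD1 at 1.14, MANF at 0.93 and XBP1 at 0.90 on the log2 scale. Known targets of nonsense-mediated decay rose in 12 of 24 and fell in 3 (13 and 3 adjusted over the list alone; camera adjusted p = 0.000108, and adjusted p = 0.0498 with an estimated correlation), among them GADD45A (1.28), GADD45B (0.90) and GAS5 (0.78). Targets of p53 rose in 7 of 20 and fell in 0 (the same adjusted over the list alone; camera adjusted p = 0.00375, and adjusted p = 0.0242 with an estimated correlation), with TP53I3 at 1.51, BAX at 1.26 and XPC at 0.997.

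Genes of G2/M and mitosis were lower in HBS1LV1 knockdown in 10 of 25 and higher in 0 (11 lower adjusted over the list alone; camera adjusted p = 4.48e-06, and adjusted p = 0.0498 with an estimated correlation). The proliferation marker MKI67 fell from 102 ± 42.7 to 24.3 ± 0.338 CPM (log2 fold change -2.07, SE 0.214), and KIF20A (-1.48), BUB1 (-0.98) and AURKA (-0.64) fell too. Hypoxia and glycolysis genes were lower in 7 of 22 and higher in 3 (8 and 3 adjusted over the list alone; camera adjusted p = 0.00492, and adjusted p = 0.0498 with an estimated correlation). NDRG1 fell from 73.4 ± 4.65 to 14.5 ± 1.11 CPM (-2.34), LDHA by 1.09, PFKFB4 fell by 1.02 and the glucose transporter SLC2A1 fell by 0.96 on the log2 scale. For 4 more lists the camera call was lost with an estimated correlation. Histones were lower in 15 of 44 and higher in 1 (16 and 1 adjusted over the list alone; adjusted p = 0.677 with an estimated correlation), with HIST1H1D at -1.09 and HIST1H2AB at -1.15 but HIST1H4J at 0.97. Immediate early and AU-rich mRNAs were higher in 12 of 31 and lower in 3 (13 and 3 adjusted over the list alone; adjusted p = 0.306 with an estimated correlation), with FOS at 1.82 and JUN at 0.69 but MYC at -1.86. RNA sensing genes were lower in 7 of 16 (also 7 adjusted over the list alone; adjusted p = 0.156 with an estimated correlation), with RNASEH2A at -0.71, ADAR at -0.67, SAMHD1 at -0.62 and ZC3HAV1 at -0.56. snoRNA host genes were higher in 9 of 18 and lower in 3 (the same adjusted over the list alone; adjusted p = 0.576 with an estimated correlation), with EPB41L4A-AS1 at 0.82 and C6orf48 at 0.74 but SNHG16 at -0.63.

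DNAH17, an axonemal dynein chain, had the largest rise in HBS1LV1 knockdown, from 4.20 ± 1.14 to 75.2 ± 1.34 CPM (log2 fold change 4.16, SE 0.193). MMP24 (3.35), ACTA2 (3.14), SH2D3C (3.13), INPP5D (2.98), PVRL4 (2.77), FBLL1 (2.70), the chemokine CXCL8 (2.70), CHGA (2.66) and LINC00346 (2.62) followed. C12orf57 fell from 135 ± 14.7 to 20.8 ± 0.900 CPM (-2.69, SE 0.214). The glutathione peroxidase GPX4 (-2.31), which protects lipids from oxidation, WSB2 (-2.66), DPP3 (-2.40), TPRG1L (-2.34), C17orf58 (-2.28), PDHA1 (-2.27) of pyruvate dehydrogenase, AIF1L (-2.26), LYPLA1 (-2.23), NR2F6 (-2.08) and the DNA methyltransferase DNMT3B (-2.08) fell too. In all, 1894 genes were higher and 1903 lower with edgeR, 662 and 423 of them by more than 2-fold. The total was 6189 when only the 6 libraries compared were fitted.

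**Figure D4:**
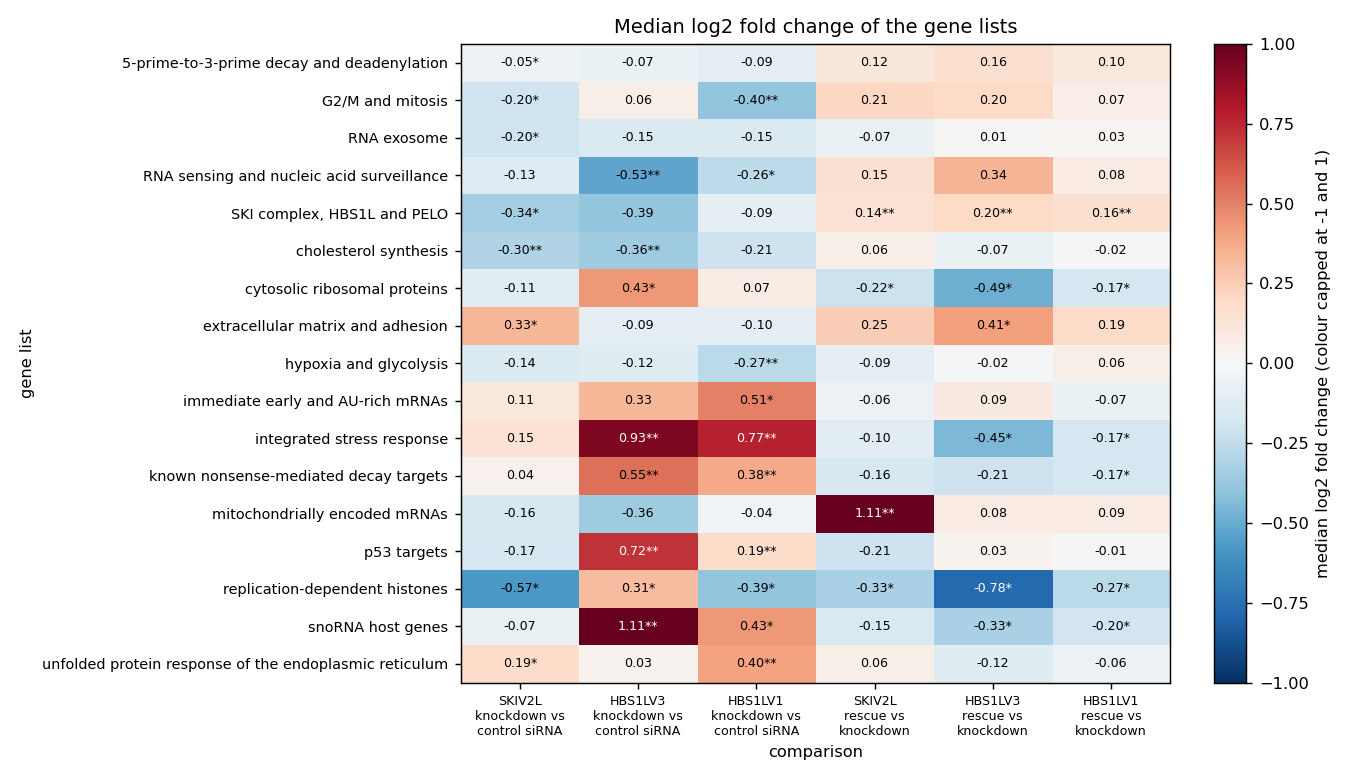
Median log2 fold change (colour and number) of the gene lists called in at least 1 of 6 comparisons; 1 asterisk marks a camera adjusted p under 0.05 and a pair of asterisks one that also passed with an estimated correlation. The integrated stress response has medians of 0.93 and 0.77 in HBS1LV3 and HBS1LV1 knockdown, and the mitochondrially encoded mRNAs have a median of 1.11 in the SKIV2L rescue line.

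The knockdowns were then compared with each other. The HBS1LV3 and HBS1LV1 knockdowns differed in 5477 genes with edgeR, 2900 higher and 2577 lower with HBS1LV3 siRNA. HDGF, a growth factor, stood at 536 ± 33.4 CPM in HBS1LV3 knockdown and 56.2 ± 7.76 CPM in HBS1LV1 knockdown (SD, n = 3; log2 fold change 3.26, SE 0.135). ACTL8 (4.05), GPX4 (2.97), ESRRB (2.89), HES7 (2.83) and PTMS (2.63) were higher by log2 fold change. DNAH17 (-3.72), CXCL8 (-3.44), TMEM198 (-3.29), LINC00346 (-3.12), IQCH (-3.05) and RAB36 (-3.01) were lower. Histones were higher in HBS1LV3 than in HBS1LV1 knockdown in 33 of 44 genes and lower in 0, snoRNA host genes were higher in 14 of 18, and genes of the unfolded protein response were lower in 14 of 18.

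HBS1LV3 and SKIV2L knockdown differed in 5031 genes with edgeR, 2512 higher and 2519 lower with HBS1LV3 siRNA. F11R was at 18.3 ± 1.202 CPM in HBS1LV3 knockdown and 1.84 ± 0.246 CPM in SKIV2L knockdown (log2 fold change 3.29, SE 0.237). FRMPD2 (5.03), ACTL8 (4.45), HIST1H3PS1 (3.34), WASIR2 (3.22) and UNC5B-AS1 (3.17) were higher, and TMEM64 (-2.88), ECI2 (-2.74), ATP6V1E1 (-2.69), GPR157 (-2.66), MLEC (-2.64) and CBFB (-2.60) were lower. Histones were higher with HBS1LV3 siRNA in 39 of 44 genes, ribosomal protein genes in 61 of 77, the integrated stress response in 16 of 25 and p53 targets in 14 of 20.

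The knockdowns were also compared by the genes that they share. In both SKIV2L and HBS1LV3 knockdown, 616 genes were higher and 395 lower, and 196 went in opposite directions. Independent lists of these sizes would give 224, 163 and 383. The shared count of 1011 was 258 and 458 without replicates A and C of each group. SKIV2L and HBS1LV1 knockdown shared 489 higher and 311 lower genes, with 153 and 123 for independent lists, and HBS1LV3 and HBS1LV1 knockdown shared 818 and 742. The correlation of log2 fold changes across genes, which are not independent replicates, was 0.374 for SKIV2L with HBS1LV3, 0.357 for SKIV2L with HBS1LV1 and 0.403 for HBS1LV3 with HBS1LV1. Simulated unchanged groups that share controls gave 0.486, 0.508 and 0.487, with 0 shared calls. The covariance was 0.120, 0.0989 and 0.158, against 0.0324, 0.0326 and 0.0323 in the simulations. With 3 control libraries, the shared part of the control cannot be removed.

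The rescue lines were compared with the parental knockdowns to ask which effects re-expression undoes. Against SKIV2L knockdown, the SKIV2L rescue line had 294 higher and 352 lower genes with edgeR. The largest changes apart from SKIV2L were in genes nearly silent in 1 of the groups. SPARC, a matrix glycoprotein, stood at 15.8 ± 1.90 CPM in SKIV2L knockdown and 0.242 ± 0.297 CPM in the rescue line (SD, n = 3; 3 counts in all), a count ratio of 80.1 (95% exact binomial interval 27.2 to 390, counting error only). The count ratio was 54.9 (18.6 to 267) for CEBPE and 47.2 (12.9 to 393) for FUOM, both lower in the rescue line, and 53.5 (17.7 to 265) for CCDC79, higher in it. SPARC was at 12.6 ± 2.01 CPM and CEBPE at 26.3 ± 9.11 CPM with control siRNA. FLNC (-3.14), TENM1 (-3.13) and LINC01033 (-2.36) were lower on the log2 scale, and ATN1 (2.03), PRR12 (1.79), ZNF703 (1.76) and RIN3 (1.72) higher.

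Mitochondrially encoded mRNAs were higher in the SKIV2L rescue line than in SKIV2L knockdown in 10 of 13 genes and lower in 0 (12 higher adjusted over the list alone; camera adjusted p = 1.9e-21, and adjusted p = 0.035 with an estimated correlation). MT-ATP6 went from 224 ± 4.72 to 605 ± 136 CPM (log2 fold change 1.43, SE 0.214), and MT-ND1 (1.22), MT-CYB (1.11) and MT-ND6 (1.04) rose too. Their sum was 1.46 ± 0.182% of normalized counts, against 0.910 ± 0.0330% in SKIV2L knockdown and 0.948 ± 0.159% with control siRNA. These are the libraries with 93.2% non-unique alignments. Ribosomal protein genes had a median of -0.22 with 1 of 77 higher, RPS16 (1.57, SE 0.308), and histones a median of -0.33 with 3 of 44 lower, HIST1H2BG (-1.05), HIST1H2AL (-0.97) and HIST1H2AE (-0.86). Counts adjusted over the list alone were the same. Both camera calls had an adjusted p = 0.681 with an estimated correlation. The list of SKIV2L, HBS1L and their partners holds the transgene among 6 genes, so its call in each rescue comparison says nothing on the partners. It had 1, 2 and 1 higher genes and 0, 1 and 0 lower ones. Apart from the targeted genes, the SKI subunit TTC37 (0.86) was higher and PELO (-0.49) lower, both in the HBS1LV3 rescue line. With the share of reads outside annotated exons as a covariate neither passed (edgeR adjusted p = 0.81 and 0.146), and TTC37 did not pass without HBS1LV3 rescue replicate B (0.264).

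The total of 646 genes in the SKIV2L rescue comparison was 227 without SKIV2L rescue replicate C, 293 without its replicate B, 302 and 259 without SKIV2L knockdown replicates A and B, and 1512 without the 2 libraries with the most reads outside annotated exons. With that share as a covariate the balance turned, to 638 higher and 419 lower genes. The 3 histone calls were each lost without SKIV2L rescue replicate C. Without the 2 libraries 13 ribosomal protein genes and 11 histones were lower. With the covariate 3 ribosomal protein genes were higher and 2 lower, and 2 histones higher and 3 lower, and neither list was called (camera adjusted p = 0.455 and 0.787).

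Against HBS1LV3 knockdown, the HBS1LV3 rescue line had 1724 higher and 2035 lower genes with edgeR. Histones were lower in 33 of 44 and higher in 0 (36 lower adjusted over the list alone), with HIST1H3F falling from 62.4 ± 5.61 to 11.5 ± 4.52 CPM (SD, n = 3; log2 fold change -2.46, SE 0.244) and HIST1H2AK (-1.67), HIST1H2BG (-1.52) and HIST1H1D (-1.04) falling too. Ribosomal protein genes were lower in 60 of 77 and higher in 0 (68 lower adjusted over the list alone), among them RPS27A (-0.70), RPS29 (-0.70), RPL3 (-0.63) and RPS15A (-0.60). snoRNA host genes were lower in 8 of 18 (11 adjusted over the list alone), with SNHG9 at -1.40 and SNHG19 at -1.13. The integrated stress response was lower in 12 of 25 and higher in 1 (14 and 2 adjusted over the list alone), with SHMT2 at -0.83, PCK2 at -0.82 and DDIT4 at -0.79. Matrix genes were higher in 10 of 30 and lower in 4 (12 and 4 adjusted over the list alone), with SPARC at 1.12 and FN1 at 0.94 but COL18A1 at -1.09. The camera calls of these 5 lists were lost with an estimated correlation (adjusted p = 0.357 for 4 of them and adjusted p = 0.378 for ribosomal proteins). Among single genes, NEAT1, a nuclear noncoding RNA, was at 285 ± 187 CPM in the rescue line and 71.2 ± 2.74 CPM in the knockdown (log2 fold change 2.00, SE 0.308). LINC01355 (2.20), ZBTB37 (2.19), TP53INP1 (1.87) and LINC00641 (1.801) were higher, and TENM1 (-2.33) and ALOX12P2 (-1.37) lower.

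The count for the HBS1LV3 rescue line was 460 without HBS1LV3 rescue replicate B, the library with 24.8% of reads outside annotated exons, 1553 without that library and HBS1LV1 rescue replicate B, and 95 with that share as a covariate. It was 784 and 1496 without HBS1LV3 knockdown replicates B and C. With the covariate 0 ribosomal protein genes, 7 histones, 1 gene of the integrated stress response and 1 snoRNA host gene were lower, and 2 matrix genes were higher and 1 was lower. Without the 2 libraries these counts were 33, 27, 10 and 4 lower, and 8 matrix genes higher and 2 lower. LINC01355, ZBTB37, TP53INP1, LINC00641 and RPS15A did not pass without replicate B alone. The list members SNHG15 (-0.57), SNHG8 (-0.55) and PHGDH (-0.74), also named by the rule, did not pass either (edgeR adjusted p = 0.0617, 0.133 and 0.0647). Without both libraries LINC01355, ZBTB37, LINC00641, RPS15A, SNHG15 and PHGDH did (edgeR adjusted p = 0.0242, 0.00202, 0.036, 0.0147, 0.0171 and 0.00803). TP53INP1 and SNHG8 did not (edgeR adjusted p = 0.0535 and 0.0643). Of 42 named calls 36 passed without both libraries and 12 with the covariate, which include HBS1L, HIST1H3F, HIST1H2AK, HIST1H2BG, TENM1 and ALOX12P2.

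Against HBS1LV1 knockdown, the HBS1LV1 rescue line had 77 higher and 108 lower genes with edgeR. TENM1, a teneurin of the cell surface, rose from 5.49 ± 1.25 to 48.4 ± 11.7 CPM (SD, n = 3; log2 fold change 3.12, SE 0.222), the opposite direction to the other rescue lines. C1orf61 (1.62), IKZF3 (1.42), ZNF711 (1.25) and COL5A2 (1.23) were higher. CEBPE fell from 17.6 ± 1.69 to 2.99 ± 0.864 CPM (-2.59, SE 0.258), and DHRS2 (-1.59), HIST1H3F (-1.45), the p53 target TP53I3 (-1.44), SYTL1 (-1.26) and SPARC (-1.23) fell too. The lists of ribosomal proteins, histones, integrated stress response, snoRNA hosts and nonsense-mediated decay targets had medians of -0.17, -0.27, -0.17, -0.20 and -0.17 and 1, 1, 0, 0 and 0 members lower, none of them called with an estimated correlation (adjusted p = 0.731, 0.731, 0.422, 0.715 and 0.422). Adjusted over the list alone, 1, 1, 7, 3 and 0 were lower, and 1 gene of the integrated stress response was higher. The called ribosomal protein gene was RPS7 (-0.45, SE 0.112). The total of 185 was 40, 45 and 29 without HBS1LV1 knockdown replicates A, B and C, and 62, 56 and 1013 without HBS1LV1 rescue replicates A, B and C, and the calls of IKZF3, ZNF711, COL5A2 and RPS7 were each lost when 1 library was left out. It was 383 with DESeq2, 304 with the covariate and 19 with the 6 libraries alone, and without the 2 libraries with the most reads outside annotated exons the balance turned to 151 higher and 125 lower genes.

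The rescue lines were compared with control siRNA to ask how many knockdown effects were still present. Of the genes higher in a knockdown, 67.6% (SKIV2L), 49.5% (HBS1LV3) and 62.3% (HBS1LV1) were also higher in the rescue line against control siRNA, and of the lower genes 67.3%, 60.8% and 68.4% were also lower. The correlation across genes between knockdown and rescue line, each against control siRNA, was 0.620, 0.673 and 0.800. Simulated unchanged groups with shared controls gave 0.454, 0.484 and 0.512, with a covariance of 0.0326, 0.0323 and 0.0325 against the observed 0.187, 0.307 and 0.280. Simulations with the knockdown effects and no undoing gave correlations of 0.858, 0.921 and 0.916 and covariances of 0.286, 0.427 and 0.359, above the observed values. Effects were undone for 62 higher and 33 lower genes of SKIV2L knockdown, 914 and 546 of HBS1LV3 knockdown, and 47 and 31 of HBS1LV1 knockdown. Independent lists of these sizes would give 28.4 and 18.9, 368 and 285, and 13.3 and 9.55. These values take no account of the knockdown libraries that both comparisons share. Genes called further from control in the rescue line numbered 24 higher and 18 lower for SKIV2L, 58 and 81 for HBS1LV3, and 2 and 6 for HBS1LV1. Simulations without undoing gave at most 1 undone gene and 0 of these. Across genes the rescue comparisons correlated at 0.320 (SKIV2L with HBS1LV3), 0.264 (SKIV2L with HBS1LV1) and 0.549 (HBS1LV3 with HBS1LV1). In these simulations they correlated at 0.0214 at most. Such shared variation is absent from the simulations, so their counts do not set the noise level of undoing. The undone count for HBS1LV3 fell from 1460 to 54 with the covariate, and to 452, 49 and 792 without replicates A, B and C of each group. That for SKIV2L fell from 95 to 1, 43 and 9 and that for HBS1LV1 from 78 to 3, 9 and 35. With the covariate these 2 counts were 186 and 142, and without the 2 libraries with the most reads outside annotated exons the 3 counts were 286 (SKIV2L), 869 (HBS1LV3) and 123 (HBS1LV1).

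Effects were undone for both SKIV2L and HBS1LV3 in 22 genes, 17 that were higher in both knockdowns and 5 that were lower, and in 0 genes of the simulations. The simulations draw each gene on its own, so this 0 does not set a noise level either. TNFRSF12A, the receptor of the cytokine TWEAK, stood at 17.8 ± 1.51 CPM with control siRNA, 47.6 ± 5.28 CPM in SKIV2L knockdown and 48.5 ± 3.60 CPM in HBS1LV3 knockdown (SD, n = 3), and at 24.9 ± 2.38 and 33.0 ± 6.85 CPM in the rescue lines. The kinase MATK stood at 38.5 ± 2.83 CPM with control siRNA, 66.5 ± 11.5 and 84.7 ± 9.79 CPM in the knockdowns, and 34.8 ± 5.90 and 48.0 ± 13.3 CPM in the rescue lines. KREMEN2, SLC9A5, TAF1C, the neuronal tubulin TUBB3, the splicing factor ESRP2 and the replication factor GINS2 were higher in the same way, and RAB6B, LARP4B, HGSNAT, which acetylates heparan sulfate, and SIK2 were lower. Without replicates A, B and C of each group, 0, 0 and 4 genes met all 4 criteria. In the rescue comparisons with SKIV2L siRNA, the calls of RAB6B, MATK, KREMEN2, LARP4B, HGSNAT, TAF1C, TUBB3, SIK2 and GINS2 were each lost when 1 library was left out. With HBS1LV3 siRNA this held for RAB6B, MATK, KREMEN2, SLC9A5, LARP4B, HGSNAT, TAF1C, TUBB3, TNFRSF12A and GINS2. With the covariate, 2 of the 22 genes still met all 4 criteria, CCNB1IP1 and METTL17, which were named after their values were seen. Without the 2 libraries with the most reads outside annotated exons, 16 of the 22 did.

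Lists with no camera call in any of these 6 comparisons were nonsense-mediated decay factors, no-go decay and ribosome quality control, interferon-stimulated genes, G1/S and DNA replication, and markers of other cell types. Of 36 interferon-stimulated genes, 23 were measured, and 1 was higher in SKIV2L knockdown and 0 lower. In HBS1LV3 knockdown 4 were higher and 8 lower, and in HBS1LV1 knockdown 1 higher and 4 lower. Of no-go decay genes, 6 of 14 were higher and 1 was lower in HBS1LV3 knockdown. Of nonsense-mediated decay factors, 3 of 14 were higher and 1 lower there. Of 24 G1/S genes, 5 were higher and 5 lower there. Of 25 markers of other cell types, 3 were measured.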

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

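Of the tests below, those of shared control noise, of transgene transcription, of re-expression and of different replicate letters, the word searches corrected for GC content, and the spread, the 2 SE limit and the summed levels used for mitochondrial RNA were chosen after the result was seen.

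Direct tests between knockdowns called 5477 genes for HBS1LV3 against HBS1LV1 and 5031 for HBS1LV3 against SKIV2L. Of genes called in both knockdowns, 288 went in opposite directions in HBS1LV3 and HBS1LV1 knockdown and 196 in HBS1LV3 and SKIV2L knockdown. Independent lists of these sizes would give 657 and 383. All were past the direct test, which opposite calls against the same controls nearly assure. Opposite log2 fold changes in HBS1LV3 and HBS1LV1 knockdown were found for HDGF (1.35 and -1.91), GPX4 (0.67 and -2.31), ESRRB (1.98 and -0.91), RAB36 (-2.28 and 0.73) and TMEM198 (-1.30 and 2.00). Among list members, SNHG3 (1.42 and -0.56), CALR (0.80 and -0.30), FN1 (-1.65 and 0.42), HMGCS1 (-1.04 and 0.38) and PAN2 (-0.49 and 0.64) did the same.

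Counters outside the genes stood above each control library in 3 groups of values. Non-unique alignments averaged 51.8% in HBS1LV3 knockdown and 93.2% in the SKIV2L rescue line. Reads outside annotated exons averaged 15.7% in the SKIV2L rescue line. Ambiguous reads averaged 27.0% in HBS1LV3 knockdown.

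Fold changes against control siRNA were shared by each knockdown and the rescue line with the same siRNA. Noise of the shared control libraries as the whole cause is argued against by a correlation across genes of 0.761 between parental cells and rescue lines for HBS1LV3 against HBS1LV1 siRNA, with no control library, and untranscribed transgenes by a smallest log2 fold change of the targeted gene of 3.89. Repression through seed matches of the siRNA may account for a part: 7-base words found in the parental knockdowns with a correction for length and GC content marked lower genes in the rescue lines by -0.102 (TGTTGGA, SKIV2L siRNA; AATGTTG on directly matched symbols, at -0.093, misses the bar of -0.10), -0.151 (AGCTTCA, HBS1LV3) and -0.155 (CCAGACA, HBS1LV1), each with a permutation p of 1e-05, the smallest possible. The searches without GC content gave -0.141 (CCAGACA) for HBS1LV1 and -0.146 for SKIV2L (AATGTTG, open as it is in 0 of 16 SKIV2L transcripts). For HBS1LV3 they gave 0.043 (permutation p = 6e-05), above the bound of -0.03 set against a seed effect. But its word TTTTAAA holds A and T alone and follows base composition, an exception made after the value was seen. The permutations take genes as independent units, so their p does not measure the spread between replicates. TGTTGGA is in 3 of 16 SKIV2L transcripts and CCAGACA in 10 and AGCTTCA in 0 of 16 HBS1L transcripts, though AAGCTTC, ranked second for HBS1LV3, is in 9. The earlier rule needed the word in a transcript of the targeted gene, while that of the GC-corrected searches did not. Under the earlier rule AGCTTCA would be open as well. Lower genes still lower in the rescue line carried TGTTGGA, AGCTTCA and CCAGACA in 24.7%, 23.9% and 23.2% (of 604, 1496 and 1232 genes). Lower genes undone by rescue carried them in 25.8%, 28.1% and 30% (of 31, 534 and 30 genes). For HBS1LV3 the word was thus not more frequent where effects persisted. For SKIV2L and HBS1LV1 the undone genes are too few to tell. The siRNA sequences are not in the sources used here, and effects of the knockdown that the transgene did not restore stay open and untested.

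The HBS1LV3 rescue line differed from HBS1LV3 knockdown in 3759 genes. Re-expression of HBS1LV3 stays open. Its contrast had a correlation across genes of 0.549 with the HBS1LV1 rescue contrast, above the bound of 0.3. But libraries of the same replicate letter correlate between these lines. Over different letters the correlation was 0.258, 0.255 and 0.381. Each of these values used a single HBS1LV3 rescue library and a single knockdown library against means of 2 HBS1LV1 libraries per group. Fewer libraries add noise, so these values cannot be held to the bound for the full contrasts. A library property that varies within groups may account for a part. The correlation with the slopes on reads outside annotated exons estimated in the other groups was 0.658 (0.215 and 0.508 for the SKIV2L and HBS1LV1 rescue contrasts). Among these other groups the share varied most in HBS1LV1 rescue (SD 2.97%, at most 1.25% in the rest), whose libraries are not independent of HBS1LV3 rescue. Gene length bias may also account for a part, with a Spearman rho of 0.477 across genes (0.357 and 0.415 in the SKIV2L and HBS1LV1 rescue contrasts). For HBS1LV3 knockdown rho was -0.204 against control siRNA, -0.242 against SKIV2L knockdown and -0.172 against HBS1LV1 knockdown. With that share as a covariate 95 genes were called, and the median size of the log2 fold changes of the 3759 genes went from 0.68 (median SE 0.191) to 0.28 (median SE 0.175), so calls ended through smaller effects and not through wider errors.

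Mitochondrially encoded mRNAs were higher in the SKIV2L rescue line than in SKIV2L knockdown, with a median log2 fold change of 1.11, and their summed share was 1.46 ± 0.182% against 0.910 ± 0.0330% (SD, n = 3). The mitochondrial rRNAs made up 23.2 ± 0.982% against 15.97 ± 0.298%, while MT-RNR1 (log2 fold change 0.61, SE 0.28) and MT-RNR2 (0.53, SE 0.177) did not pass the edgeR test (adjusted p = 0.26 and 0.0945). Less complete removal of rRNA needs rRNAs that rise at least as much as the mRNAs. The bound set against it beforehand was a rise of the rRNAs at least 0.5 smaller. The difference was -0.578 (SE 0.095) from the median fold change, which passes that bound by less than its SE. From summed levels it was -0.134 (SE 0.082), so less complete removal stays open. More mitochondrial RNA of all kinds cannot be told apart from it, as the absolute difference of 0.541 (SE 0.062) passes its bound of 0.5 by less than its SE, while medians over the levels of each library gave -0.85 (SE 0.108). SKIV2L re-expression stays open and untested.

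With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. In each of the 11 comparisons 1 split, the real one, gave as many genes. The highest other split gave 0 for the SKIV2L (real 2229) and HBS1LV3 (5309) knockdowns and 1 for HBS1LV1 (3797), and 0 for the rescue lines against knockdown (646, 3759 and 185) and between knockdowns (5477 and 5031). For the rescue lines against control siRNA it gave 2 (3352), 2 (5392) and 20 (4121).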

How the results depend on the processing

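The covariate, the fits without libraries chosen by that share or without the SKIV2L rescue libraries, and RLE factors for gene lists were chosen after the result was seen; scaling to spike-ins was not run. No list call reversed. No call of a named or targeted gene reversed where it was followed, with DESeq2, RLE factors, the block, the 6 libraries alone or 1 library left out. With the covariate and without the 2 libraries with the highest share, these calls were followed only in the rescue lines against knockdown. They were not followed with the other filters or without the SKIV2L rescue libraries. The balance of higher and lower genes turned from 294 and 352 to 638 and 419 with the covariate (SKIV2L rescue line) and from 77 and 108 to 151 and 125 without the 2 libraries (HBS1LV1 rescue line). In HBS1LV3 knockdown it turned from 2775 and 2534 to 3355 and 3388 without the 2 libraries. Some near-even balances crossed 50% with other scalings, such as HBS1LV1 knockdown (49.9% higher with TMM, 50.2% with RLE factors). Of 16 counts, 16 stayed within 1.5 times with RLE factors, the CPM filter and the replicate block, and 14 with DESeq2 and without a filter. Of 42 list calls, 17 held with an estimated correlation, 34 with fry, 42 with the block and with RLE factors, 38 with the covariate and 41 without 2 libraries. Of calls of named or targeted genes, 51 of 298 were lost without 1 library, 17 of 298 with the 6 libraries alone, 5 of 304 with the block, 1 of 298 with RLE factors and 0 of 302 with DESeq2. RLE and DESeq2 shifted the median log2 fold change by at most 0.014 in size (-0.014, SKIV2L rescue line against control siRNA).

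In the order SKIV2L, HBS1LV3, HBS1LV1, values that moved by over 1.5 times follow. With the 6 libraries alone, the knockdowns gave 3349 (SKIV2L) and 6189 (HBS1LV1), the rescue lines against knockdown 992, 1197 and 19, the HBS1LV1 rescue line against control 2689, undone effects 180, 631 and 5, and genes shared by SKIV2L and HBS1LV3 knockdown 1524. With the covariate, SKIV2L knockdown gave 3869, the rescue lines 1057, 95 and 304, undone effects 186, 54 and 142, shared genes 1839 and genes undone for both 4. Without the 2 libraries, SKIV2L knockdown gave 3647, rescue lines 1512 and 1553, undone effects 286, 869 and 123, shared genes 1712 and undone for both 47. The HBS1LV1 rescue line gave 383 with DESeq2, 605 without a filter and 112 without the SKIV2L rescue libraries, and HBS1LV1 effects undone were 150 with DESeq2 and 188 without a filter. At 0.1, undone effects were 188, 2406 and 246, and undone for both 56. At 0.01 they were 19, 336, 11 and 4, with 493 shared genes. The cause was not tested, except that a stricter threshold calls fewer genes. Without 1 library, lowest and highest were 1479 and 1761, 3876 and 5100, and 2736 and 3035 for the knockdowns, 227 and 549, 460 and 5191, and 29 and 1013 for rescue against knockdown, 4241 and 5002, and 3683 and 4642 between knockdowns, and 2272 and 3086, 4106 and 5433, and 2973 and 4456 for rescue against control. Without 1 replicate letter, undone effects were 1 to 43, 49 to 792 and 3 to 35, genes shared by both knockdowns 258 to 759, and undone for both 0 to 4.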

Other observations

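The GC-corrected word searches and the match through older symbols were chosen after the result was seen.

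The direct test called 35.7% of all genes between HBS1LV3 and HBS1LV1 knockdown and 32.8% between HBS1LV3 and SKIV2L knockdown, and no test of whole lists was run on these comparisons. Genes of G2/M and mitosis were higher with HBS1LV3 siRNA than with HBS1LV1 siRNA in 12 of 25 and lower in 1, p53 targets higher in 10 of 20 and lower in 1, and ribosomal protein genes higher in 34 of 77 and lower in 1. Against SKIV2L knockdown, HBS1LV3 knockdown had lower matrix and adhesion genes in 13 of 30 and higher in 1, and lower genes of the unfolded protein response in 9 of 18 and higher in 1.

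Histones made up 2.21 ± 0.182% of normalized counts with control siRNA (SD, n = 3), 2.47 ± 0.308% in HBS1LV3 knockdown and 1.57 ± 0.0643% in HBS1LV1 knockdown. In the rescue lines they made up 1.13 ± 0.176% (SKIV2L), 1.44 ± 0.441% (HBS1LV3) and 1.34 ± 0.381% (HBS1LV1). TENM1 averaged 7.46 CPM in SKIV2L knockdown, 5.84 CPM in HBS1LV3 knockdown and 5.49 CPM in HBS1LV1 knockdown, against 0.803, 1.11 and 48.4 CPM in the matching rescue lines.

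The 7-base words of the GC-corrected searches were chosen for marking lower genes, so their shares in these genes are no test. TGTTGGA was in the 3' UTR of 24.5% of lower, 9.69% of higher and 14.8% of all genes searched for SKIV2L knockdown, AGCTTCA of 24.3%, 7.06% and 14.5% for HBS1LV3 knockdown, and CCAGACA of 22.3%, 9.61% and 12.96% for HBS1LV1 knockdown. Their z values were -9.44, -11.7 and -11.9 with their own siRNA and 0.176 and -0.147, -0.393 and 0.697, and 0.771 and -0.548 with the other siRNAs. In the searches without GC content, z values with the other siRNAs were -6.24 and -1.64 (AATGTTG), -8.69 and -7.003 (TTTTAAA) and, in the opposite direction, 3.25 and 3.33 (CCAGACA). Of 12 named lower genes in each knockdown, 6, 9 and 6 carry the word. F11R, QDPR, AKR1B1, UBE2E2, HIGD1A and RRS1 carry TGTTGGA, ECI2, CBFB, SNX10, TPRG1L, ATP6V1E1, ATP5B, RPL14, PEF1 and ADIPOR1 carry AGCTTCA, and WSB2, DPP3, C17orf58, PDHA1, AIF1L and LYPLA1 carry CCAGACA. Each search was run on 2 gene sets: with directly matched symbols alone (12251 genes), AATGTTG (-0.093) ranked first for SKIV2L with GC content, and CAGACAA (-0.107, in 0 of the HBS1L transcripts) for HBS1LV1 without it.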
